A study of Mus musculus with 10 samples.

How the data were processed

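The series measured histone marks in normal mouse liver by chromatin immunoprecipitation and sequencing (ChIP-seq). H3K27Ac, acetylation of histone H3 at a lysine of its tail, marks active promoters and enhancers. H3K4me2, a dimethylated lysine of the same histone, marks promoters and enhancers more broadly. The 10 samples comprised 1 fresh frozen H3K27Ac library and 9 samples of formalin-fixed, paraffin-embedded (FFPE) liver. Of the latter, 6 were H3K27Ac libraries made with FiTAc-seq, in which sections were heated in detergent buffer and then sonicated. The other FFPE samples were 1 H3K27Ac and 1 H3K4me2 library made with FiT-seq, in which proteinase K was used to break up the tissue, and 1 input DNA, which was not analysed here. Groups came from the sample titles. The FiTAc-seq libraries were homogenized at 50 °C or 65 °C with 5 or 40 min of sonication, or at 80 °C with 40 min, and only 65 °C with 5 min had 2 libraries.

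Reads were aligned with BWA and peaks were called with MACS2 on the mouse build mm9, per the submitters' processing notes. Versions, thresholds, background settings and the use of a control library were not given in the sources used here. Libraries were prepared with either of 2 commercial kits, per the labels' protocols, which do not say which library had which kit. The authors deposited 1 peak list per library, so peaks were called per library and not on pooled samples. Each list has 5 columns, for the chromosome, start, end, a peak name and a value. The deposited value of each peak was read as the −log10 of its q-value, because the long lists end at or just above 2 and the values fall in steps that widen upward. It is the authors' own score, and it depends on each library's depth and background. Within a list, it was used to describe, rank and filter peaks and to weight large regions. Between lists, its ranks over shared peaks were correlated. No fold enrichment, p-value or summit is in the lists. The analysis design, fixed before the data were examined, had assumed a fold enrichment, and the −log10 q-value took its place.

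Peaks on chromosomes 1 to 19, X and Y were kept, and mitochondrial peaks were counted apart. Starts are given 1-based, on mm9. Lists were compared at equal length with the 5000 peaks of highest −log10 q-value of each, ties being broken in a fixed random order. Lists with fewer than 5000 peaks were used whole and set against all fresh frozen peaks. Peaks were counted as shared when they overlapped by at least 1 bp. Shares carry Wilson 95% intervals, which cover counting error only, since the sequencing depth is unknown and peaks along a chromosome are not independent. The overlap that chance gives was taken as the mean of 100 circular shifts of one list along each chromosome. Rank correlations are Spearman's rho across shared peaks, which are not replicates. Large regions were built by stitching peaks at gaps of up to 12500 bp and ranking them by the sum of −log10 q-value times length. Those beyond the point where the scaled ranked curve has a slope of 1 were called large. This uses peaks in place of read signal, so the regions are not those a signal-based super-enhancer caller would give.

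Every condition other than 65 °C with 5 min had 1 library, so no p-value compares conditions. Differences were set against the standard deviation (SD) of the 2 libraries at 65 °C and 5 min. Nothing says whether these came from separate animals or blocks, so their spread may be technical. The regions named in the text followed a rule fixed before the data were examined. It took the 5 highest large regions of fresh frozen liver and the 5 highest fresh frozen peaks in none of the 5 long FiTAc-seq lists. It also took the 5 highest peaks of both 65 °C, 5 min libraries without a fresh frozen peak and the 3 highest peaks of each list with fewer than 5000. Gene annotation of mm9 was not used here, and coordinates were not moved between builds. Regions therefore carry no gene names, and the planned lists of liver genes and promoter windows were not run.

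Alternatives covered a −log10 q-value of at least 5, merging of peaks within 500 bp, autosomes only and lists of 2000 or 10000 peaks. They also covered an overlap of 50% of the shorter peak, a stitching distance of 5000 bp, the 500 highest regions, ranking regions by length, and leaving out either library of the pair. Chosen after seeing the data were the midpoint within the other peak, closing gaps of up to 76 bp, merging and other overlap rules for the differences between conditions, and leaving out peaks that met a FiT-seq H3K27Ac peak. The overlap, shift, correlation and stitching steps were tested on simulated lists of 5000 peaks. They returned a made share of 60% as 60% and a made chance overlap of 1.10% as 1.16%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.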

Results

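H3K27Ac was profiled in 1 fresh frozen and 7 FFPE libraries of normal mouse liver, and H3K4me2 in 1 FFPE library. The series was designed to find the homogenization temperature and sonication time for FiTAc-seq, to show how the proteinase K protocol (FiT-seq) performed for both marks, and to set both against fresh frozen tissue that the series calls matched. Whether the fresh frozen and FFPE tissue came from the same animal was not stated, so shares between them may compare different animals. The data are 9 lists of peaks with a −log10 q-value each. Read depth is unknown, and apart from 65 °C with 5 min each condition had no replicate.

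Fresh frozen liver gave 48239 H3K27Ac peaks. The FiTAc-seq lists held 38409 peaks at 50 °C and 5 min, 65332 at 50 °C and 40 min, and 64146 at 65 °C and 40 min. The pair at 65 °C and 5 min held 60244 and 56632 peaks, a mean of 58438 ± 2554 (SD, n = 2). These counts depended on how peaks were delimited. With peaks merged within 500 bp, fresh frozen liver had 33163, the pair a mean of 33898, and the lists of 40 min 32453 at 50 °C and 32176 at 65 °C. The 50 °C, 5 min list then had 23319. At 80 °C and 40 min only 65 peaks were listed. FiT-seq gave 115 peaks for H3K27Ac and 11746 for H3K4me2. Peaks covered 20.5 Mb in fresh frozen liver and 42.2 ± 2.83 Mb (SD, n = 2) at 65 °C and 5 min. Of the 5000 highest peaks in either library of the pair, 83.9% met one of the other library's 5000, as the mean of both directions. Chance gave 1.13% to 1.15%. The rank correlation of −log10 q-values over their 40665 shared peaks was 0.72.

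Most fresh frozen H3K27Ac sites were found again in FFPE tissue by FiTAc-seq. At 65 °C and 5 min, 71.6% ± 2.00 (SD, n = 2) of all fresh frozen peaks met a peak of the library. The share was 73.2% (95% interval 72.8 to 73.6) at 50 °C and 40 min and 72.0% (71.6 to 72.4) at 65 °C and 40 min. It was 43.7% (43.2 to 44.1) at 50 °C and 5 min. Chance gave between 1.27% and 2.68% in these 5 long lists. Recovery depended on the rank of the fresh frozen peak. Among the 1000 highest, 98.6% were met in each library at 65 °C and 5 min and 96.6% in the 50 °C, 5 min list. From rank 30001 on, the shares were 53.1% and 48.9% in the pair and 21.8% at 50 °C and 5 min.

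**Figure D1:**
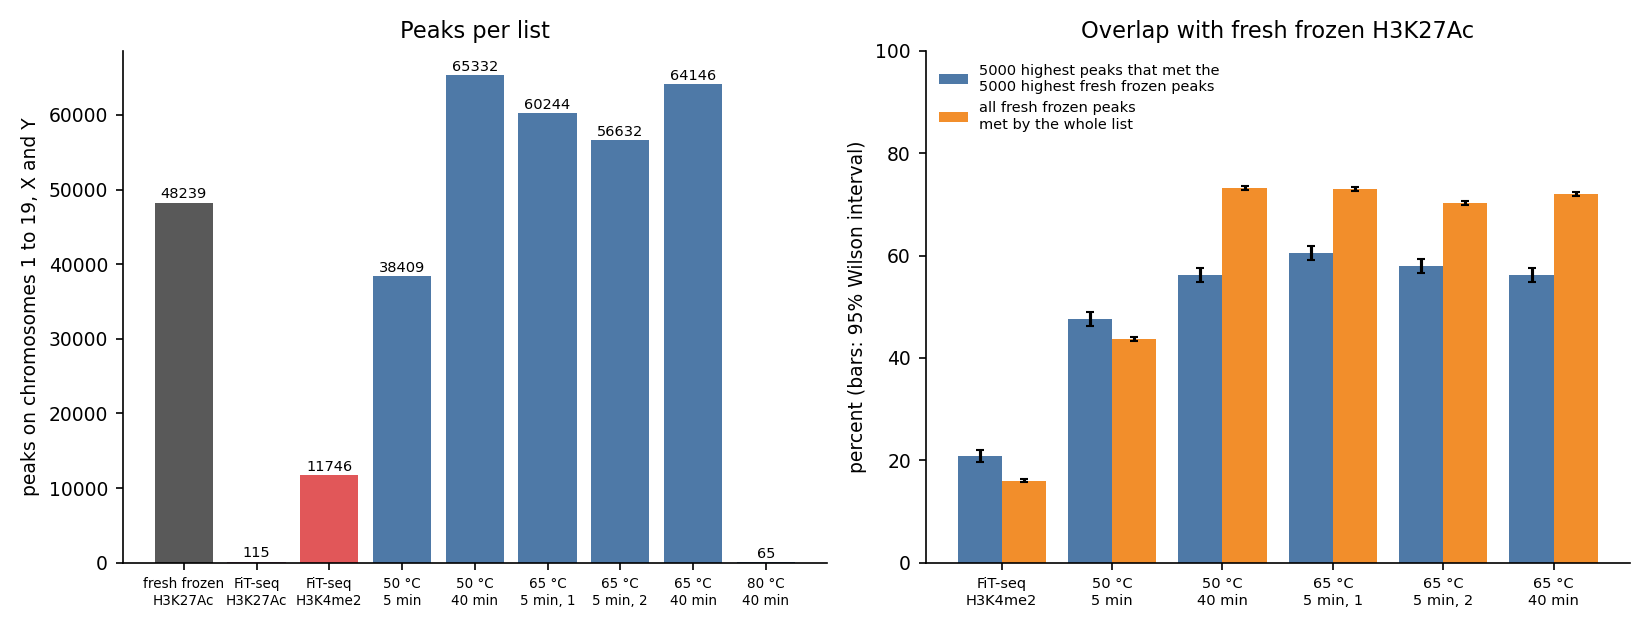
The left panel shows the number of peaks in each list, by sample, and the right panel the percent of overlap with fresh frozen H3K27Ac for the lists with at least 5000 peaks, with 95% Wilson intervals (counting error only). Blue bars at right are the 5000 highest peaks that met the 5000 highest fresh frozen peaks, between 20.8% and 60.4%, and orange bars are all fresh frozen peaks met by the whole list, between 16.0% and 73.2%.

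**Figure D2:**
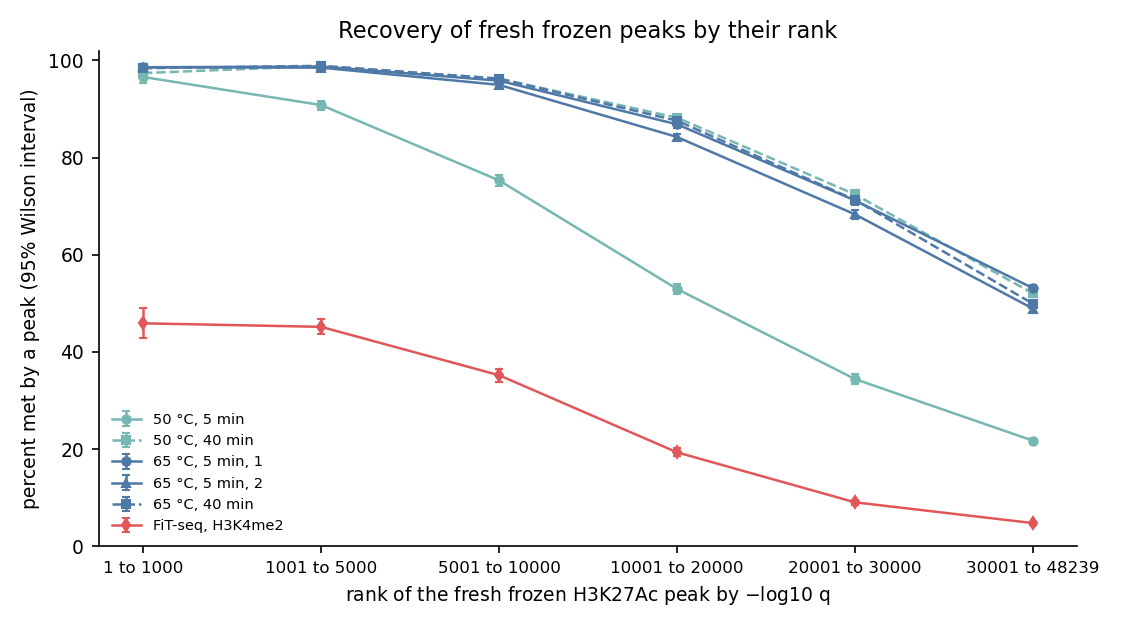
Percent of fresh frozen H3K27Ac peaks met by a peak of each list (vertical axis) in classes of the fresh frozen peak's rank by −log10 q-value (horizontal axis), with 95% Wilson intervals. Of the 1000 highest, 96.6% to 98.6% were met in the 5 long FiTAc-seq lists and 45.9% in the FiT-seq H3K4me2 list.

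The fresh frozen peaks found in all 5 long FiTAc-seq lists numbered 19828, or 41.1%, with a median width of 513 bp. Those in none numbered 8010, or 16.6%, with a median width of 220 bp. Their median −log10 q-values in the fresh frozen list were 18.4 and 5.74. The 5 highest of the missing peaks were sites of 246 to 926 bp that ranked 5, 15, 17, 86 and 90 in fresh frozen liver. They lay at chromosome 12, 3109899 to 3110174, chromosome 12, 68160143 to 68160909, chromosome 9, 24346412 to 24346670, chromosome 15, 74916577 to 74917502, and chromosome 9, 3015197 to 3015442. All 5 also held a peak among the 30 highest of the FFPE H3K4me2 list, with ranks of 7, 12, 19, 18 and 27. The FiT-seq H3K27Ac list held a peak at 4 of them, all but the chromosome 12 site at 68160143. Read pile-up that does not depend on the antibody was not tested at these sites, so they may not be H3K27Ac sites lost in FFPE tissue.

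In the other direction, 40665 peaks of the first 65 °C, 5 min library were shared with the second, and 57.6% (57.1 to 58.1) of them met a fresh frozen peak. The remaining 17248 were narrower and lower, with a median width of 329 bp against 982 bp and a median −log10 q-value of 6.73 against 17.9. Of these, 81.3% (80.7 to 81.9) lay within 5000 bp of a fresh frozen peak, where chance gave 12.7%. The 50 °C, 40 min list held 61.4% of them, the 65 °C, 40 min list 58.3% and the 50 °C, 5 min list 29.1%. The highest by mean rank was a 543 bp site at chromosome 17, 4626111 to 4626653. It ranked 1639 and 38 in the pair, was also the highest peak of the FiT-seq H3K27Ac list and ranked 37 for H3K4me2. Read pile-up that does not depend on the antibody was not tested at this site. Next came chromosome 2, 172978428 to 172982001, a 3574 bp peak with ranks of 942 and 1802 in the pair and 1703 at 65 °C and 40 min. It had no H3K4me2 peak. The others were chromosome 13, 51298081 to 51298426, chromosome 7, 26958475 to 26960568, and chromosome 5, 146229090 to 146230616. Each of these 5 sites had a peak in all 5 long FiTAc-seq lists, but often a low one. In the order given, their ranks were 33559, 8469, 28512, 4567 and 33371 at 50 °C and 40 min. At 65 °C and 40 min they were 9555, 1703, 20079, 7829 and 24687.

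Sonication time was compared at 50 °C and at 65 °C. At 50 °C, 40 min gave 26923 more peaks than 5 min, where the SD of the pair at 65 °C was 2554. The recovery of fresh frozen peaks was 43.7% after 5 min and 73.2% after 40 min. Of the 5000 highest peaks, 47.6% (46.2 to 49.0) met the 5000 highest fresh frozen peaks after 5 min and 56.3% (54.9 to 57.6) after 40 min, a difference of 8.70 percentage points against an SD of 1.81. Nearly all of these peaks met some fresh frozen peak, with 94.0% (93.3 to 94.6) after 5 min and 99.1% (98.8 to 99.3) after 40 min. At 65 °C, 40 min gave 5708 more peaks than the mean of the pair. Recovery was 72.0%, within the range of the pair (70.2% to 73.0%). The overlap of the 5000 highest peaks was 56.2% (54.9 to 57.6) after 40 min and 59.2% ± 1.81 (SD, n = 2) after 5 min, a difference of -2.92 points. Against all fresh frozen peaks the shares were 99.1% after 40 min and 99.3% and 99.0% in the pair.

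Both of these 65 °C differences changed sign under another setting, the count with the way peaks were delimited and the overlap with the rule for a shared peak. The lists of 40 min at 50 °C and 65 °C had peaks as close as 36 bp, whereas fresh frozen liver, H3K4me2 and the 3 lists of 5 min had none closer than 76 bp. With gaps of up to 76 bp closed in every list, the count at 65 °C was -1332 for 40 minus 5 min. Where the midpoint had to lie within the other peak, the difference in overlap was 1.74 points. With peaks merged within 500 bp, the values at 65 °C were -1722 peaks and -0.35 points. At 50 °C the directions held, with 19765 peaks after closing gaps, 9134 after merging and 5.46 points with the midpoint rule. The listing of peaks and sonication therefore cannot be told apart in the count at 65 °C, whereas the smaller gaps did not account for most of the count difference at 50 °C. Because the smaller gaps occurred in the lists of 40 min at both temperatures, sequencing or peak calling may have differed with sonication time. Such a difference cannot be told apart from sonication in the counts, recovery or overlap at 50 °C or 65 °C.

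The highest peaks differed in width. The 5000 highest had a median width of 733 bp in fresh frozen liver and 2256 ± 44.9 bp (SD, n = 2) at 65 °C and 5 min. Medians were 987 bp at 50 °C and 5 min, 1557 bp at 50 °C and 40 min, and 1546 bp at 65 °C and 40 min. With gaps of up to 500 bp closed in every list, these 3 medians were 1724, 2521.5 and 2455.5 bp, and that at 65 °C and 5 min was 2861 bp. One of the 5000 highest peaks in the first 65 °C, 5 min library met 1.92 fresh frozen peaks on average, and at 65 °C and 40 min 1.56. Of these peaks, 61.2% and 40.3% met at least 2. Settings of the peak calling were not given, and the scores of the fresh frozen and FiTAc-seq lists differed in form, as described below. A difference in calling therefore cannot be told apart from tissue in the widths of fresh frozen and FFPE peaks.

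**Figure D3:**
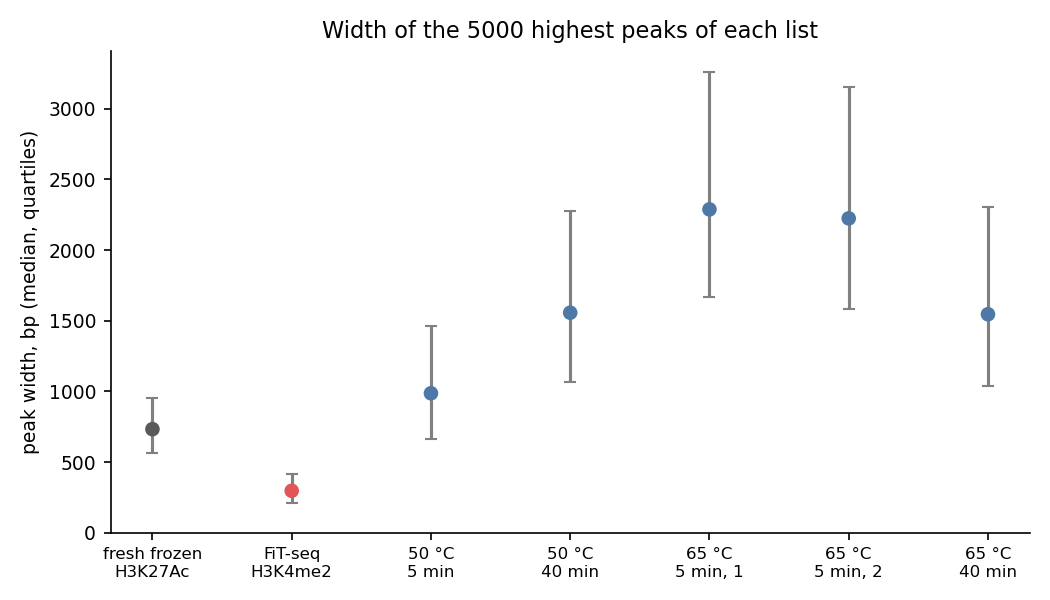
Median width in bp (points) and quartiles (bars) of the 5000 highest peaks of each list with at least 5000 peaks, with samples along the horizontal axis. The median was 733 bp in fresh frozen liver, 297 bp for FiT-seq H3K4me2 and between 987 and 2288 bp in the FiTAc-seq lists.

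Temperature was compared at each sonication time. At 5 min, 65 °C gave 20029 more peaks than 50 °C, and the overlap of the 5000 highest peaks with fresh frozen liver was 11.6 points higher. Both exceeded the SD of the pair (2554 peaks and 1.81 points). With the midpoint rule the difference in overlap was 3.58 points, and with peaks merged within 500 bp the count difference was 10579. The 5000 highest peaks were also wider at 65 °C and 5 min, with a median of 2256 bp against 987 bp. How far width sets the difference in overlap was not tested. At 40 min, the lists at 65 °C and 50 °C differed by -1186 peaks and -0.04 points, which is less than those SDs. With only peaks of a −log10 q-value of at least 5, however, the count difference was -8113, larger than the SD. With 2000 peaks per list the difference in overlap was -1.95 points. That is larger than the SD at 5000 peaks but smaller than the 2.56 points by which the 2 libraries of the pair differed there. Their 5000 highest peaks met one another in 81.0% of cases. The corresponding share of the replicate pair was 83.9%.

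At 80 °C and 40 min, fresh frozen H3K27Ac sites were almost absent. The list met 54 fresh frozen peaks, or 0.112% (0.0858 to 0.146). Of its 65 peaks, 56 met a fresh frozen peak, or 86.2% (75.7 to 92.5), where chance gave 1.46%. The highest was chromosome 2, 98502732 to 98503138, with a −log10 q-value of 35.2, a site ranked 30 in fresh frozen liver and 24 for H3K4me2. The next was chromosome 9, 35112751 to 35113151, which was the highest peak both in fresh frozen liver and for H3K4me2. These sites on chromosomes 2 and 9 also ranked 35 and 36 in the FiT-seq H3K27Ac list, and neither had a peak at 50 °C and 40 min. The third was chromosome Y, 2883708 to 2883883, and 9 of the 65 peaks lay on chromosome Y. Read pile-up that does not depend on the antibody was not tested for this list. The share of 86.2% may therefore not reflect H3K27Ac kept at 80 °C.

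The proteinase K protocol was tested for both marks. For H3K27Ac, 39 of its 115 peaks met a fresh frozen peak, or 33.9% (25.9 to 43.0), and 104 met an H3K4me2 peak of the same protocol, or 90.4% (83.7 to 94.6). Chance gave 1.03% and 0.22%. The 50 °C, 40 min list met 4.35% of them, and the first and second 65 °C, 5 min libraries 40.9% and 54.8%. After the chromosome 17 site, which starts at 4626098 in this list, the highest was chromosome 17, 39979886 to 39985824, a 5939 bp peak ranked 111 for H3K4me2 and 16475 in fresh frozen liver. The third was chromosome 3, 5860374 to 5860868, ranked 6 for H3K4me2 and found in none of the 5 long FiTAc-seq lists. The first stretch of chromosome 9 with peaks, 2999961 to 3038311, held 13 of the 115 peaks, 23 H3K4me2 peaks and 24 fresh frozen peaks. The long FiTAc-seq lists held 0 to 6 there.

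H3K4me2 peaks lay largely on H3K27Ac sites. Of the 11746, 9958 (84.8%) met an H3K27Ac peak of fresh frozen liver or of a long FiTAc-seq list. Fresh frozen liver alone met 70.0% (69.1 to 70.8), the first 65 °C, 5 min library 76.3% (75.6 to 77.1) and the 50 °C, 5 min list 48.4% (47.5 to 49.4). The overlap at equal length was lower and depended on that length. Of the 5000 highest H3K4me2 peaks, 20.8% (19.7 to 22.0) met the 5000 highest of fresh frozen H3K27Ac, and 21.0% and 19.5% those of the pair. With fresh frozen H3K27Ac it was 7.95% at 2000 peaks and 38.6% at 10000, and 72.9% of the 5000 met some fresh frozen peak. At 5000 peaks it was 14.6% at 50 °C and 40 min, 14.2% at 65 °C and 40 min, and 12.7% at 50 °C and 5 min. The rank correlation of H3K4me2 with fresh frozen H3K27Ac over shared peaks was -0.02, and with the pair at 65 °C and 5 min it was -0.145 and -0.146. Between the 65 °C, 5 min libraries and fresh frozen liver the values were 0.66 and 0.63. Those of the other lists with fresh frozen liver were 0.59 and 0.58 for 40 min at 50 °C and 65 °C, and 0.38 for 50 °C and 5 min. The 100 highest H3K4me2 peaks met fresh frozen peaks in 70 cases, or 70.0% (60.4 to 78.1), close to the 72.9% (71.7 to 74.1) of the next 4900. In 4 FiTAc-seq lists the shares of the 100 and of the next 4900 were further apart, at 30.0% against 75.3% and 72.2% in the pair at 65 °C and 5 min, 26.0% against 67.3% at 65 °C and 40 min, and 4% against 68.7% at 50 °C and 40 min.

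Large stitched regions were compared because the series addressed super-enhancers. Fresh frozen liver gave 1694, with a median length of 13818.5 bp and 19.2% of all its peaks. The long FiTAc-seq lists gave 666 to 777, with median lengths between 20461 and 36162 bp. Of the fresh frozen regions, 26.3% (24.3 to 28.5) and 25.9% (23.8 to 28.0) met a large region of the 65 °C, 5 min pair, where chance gave 1.82% and 1.74%. The share was 28.5% (26.4 to 30.6) at 50 °C and 40 min, 25.4% (23.4 to 27.6) at 65 °C and 40 min, and 24.0% (22.0 to 26.1) at 50 °C and 5 min. Of the FFPE regions, 63.2% and 61.2% in the pair met a large fresh frozen region. Between the libraries of the pair, the shares were 87.5% and 85.4%. Of the 1694 fresh frozen regions, 228 met a large region in all 5 long FiTAc-seq lists and 1040 in none. These shares depended on the settings. Stitching at 5000 bp gave between 13.8% and 17.4% in the FiTAc-seq conditions, and ranking by length alone between 36.8% and 51.4%. The main shares set 1694 regions against 666 to 777, whereas the 500 highest regions of each list gave between 32.8% and 36.2%.

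The highest fresh frozen region was a 63.6 kb stretch of 20 peaks at chromosome 7, 148599450 to 148663055. It met a large region in all 5 long FiTAc-seq lists, with ranks of 51 and 50 among stitched regions at 65 °C and 5 min and 31 at 50 °C and 5 min. Chromosome 11, 70460076 to 70526960, with 14 peaks, and chromosome 9, 107436365 to 107501333, with 12 peaks, were also large in all 5. The latter ranked 6 and 12 in the pair and 272 at 65 °C and 40 min. Chromosome 11, 120318645 to 120411515, a 92.9 kb stretch of 22 peaks, was large in 4 lists and ranked 699 at 50 °C and 5 min. The region ranked 2 in fresh frozen liver, chromosome 9, 2999961 to 3038311, was large in none of the 5. It ranked 1 for H3K4me2, and 12021 and 11435 at 65 °C and 5 min. Read pile-up that does not depend on the antibody was not tested for this region either.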

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

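The bound on gap closing below was set before its value was seen, and the tests on fragment length and sensitivity after. The effect of 40 against 5 min of sonication on the overlap with fresh frozen liver differed in direction between temperatures, at 8.70 points at 50 °C and -2.92 points at 65 °C. The difference between these effects was not tested, since 3 of the 4 conditions had 1 library, and the 65 °C value turned to 1.74 points with the midpoint rule.

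The median width of the 5000 highest peaks after 40 min was 1.58 times that after 5 min at 50 °C and 0.685 times at 65 °C, where both libraries of 5 min had wider peaks. This difference was not tested either, and the 50 °C ratio was 1.75 and 1.46 with gaps of up to 76 and 500 bp closed. Splitting at smaller gaps in the lists of 40 min was argued against as the whole cause, because the 65 °C ratio was still 0.752 with gaps of up to 76 bp closed in every list, though it rose to 0.858 with gaps of up to 500 bp closed, so splitting may account for part of it. Fewer fresh frozen sites found was argued against as well, since the 65 °C, 40 min list recovered 72.0% of the fresh frozen peaks, within the range of the pair. Recovery counts any overlap of 1 bp, so it cannot decide on lower sensitivity at the edges of peaks, which stays open. Peaks covered 34.6 Mb at 65 °C and 40 min, against 44.2 and 40.2 Mb in the pair. Shorter fragments after longer sonication remain open: the ratio of 1.58 at 50 °C goes against them, but the 5 min list there recovered 43.7% of the fresh frozen peaks against 73.2%, so that ratio may follow the weaker list, and a difference in sequencing between the lists cannot be told apart from sonication time.

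Mitochondrial peaks, which no comparison used, numbered 13 in the second library at 65 °C and 5 min, and 11 in fresh frozen liver, against 0 in the first library at 65 °C and 5 min. FiT-seq had 5 for H3K27Ac and 5 for H3K4me2, the 50 °C, 5 min list 1, and the 3 lists of 40 min none.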

How the results depend on the processing

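Shares moved with the length of the lists, the overlap rule and the stitching, and 3 differences between conditions changed sign. The cause was not tested, except that merging joins peaks and so lowers counts by construction. Of 206 alternatives, 105 were classed as moving a value, 6 as changing its sign and 95 as neither. For shares and for differences between conditions, the measure was the counting interval or the SD of the pair. Peak counts were held to a looser measure, so counts among the 95 can lie beyond their spread. The mean count at 65 °C and 5 min, 58438 ± 2554 as listed, was 44463.5 with a −log10 q-value of at least 5, and was classed as neither. Chosen after seeing the data were the midpoint rule, closing of gaps and leaving out peaks at FiT-seq H3K27Ac sites. So were merging and the rule of 50% of the shorter peak for differences between conditions. Ranking by fold, a fold of at least 5, the summit rule and promoter windows were not run, since the lists hold no fold or summit and no mm9 annotation was used. Lists with fewer than 2000 peaks gave no value at other lengths. Depth is unknown, and lists were not thinned to equal depth. Where 4 FiTAc-seq values follow one another, they are for 50 °C and 5 min, 50 °C and 40 min, 65 °C and 40 min, and the mean at 65 °C and 5 min.

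With a −log10 q-value of at least 5, counts were 7149 for H3K4me2 and 23006 at 50 °C and 5 min. Fresh frozen recovery was 12.0% for H3K4me2, 38.0% at 50 °C and 5 min and 75.3% at 50 °C and 40 min. The count differences were 32369 and 2798.5 for 40 minus 5 min at 50 °C and 65 °C, and, at 40 min, -8113 for 65 °C minus 50 °C and -47217 for 80 °C minus 65 °C. Merging within 500 bp gave 23319, 32453, 32176 and 33898 peaks, and 33163 in fresh frozen liver. The count differences were then 9134 and -1722 for sonication at 50 °C and 65 °C, 10579 for 65 °C minus 50 °C at 5 min, and -32113 for 80 °C minus 65 °C. With gaps of up to 76 bp closed, they were 19765 and -1332 for sonication and -56852 for 80 °C minus 65 °C. For the overlap with fresh frozen liver, merging gave -0.35 points for sonication at 65 °C and 8.21 for temperature at 5 min. The temperature difference at 40 min, -0.04 points as listed, was 0.28 after merging and 0.08 after closing gaps, both within the SD of the pair.

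With 2000 peaks per list, the replicate overlap was 76.9%, and the overlap with fresh frozen liver 32.8%, 40.8%, 38.9% and 40.3%, and 7.95% for H3K4me2. Temperature differences in this overlap were 7.53 points at 5 min and -1.95 at 40 min. The latter was larger than the SD of the pair at 5000 peaks (1.81) but smaller than the difference between its 2 libraries there (2.56). The H3K4me2 overlap was 3.70%, 3.35%, 3.10% and 4.48%. With 10000 peaks, the replicate overlap was 86.8%, and the overlap with fresh frozen liver 53.0%, 63.6%, 63.7% and 66.5%, and 38.6% for H3K4me2. Differences were 10.6 points for sonication at 50 °C, 13.5 for temperature at 5 min and 0.14 for temperature at 40 min, the last reversed from -0.04 but within the SD of the pair. The H3K4me2 overlap was 25.1%, 33.0%, 32.4% and 44.6%.

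With 50% of the shorter peak, fresh frozen recovery was 40.3%, 70.9%, 69.7% and 68.4%, and 14.0% for H3K4me2. The H3K4me2 overlap was 17.4% with fresh frozen liver and 11.3%, 13.5% and 13.0% with the first 3 FiTAc-seq lists. With the midpoint rule, the overlap with fresh frozen liver was 41.0%, 46.5%, 46.3% and 44.6%, and 17.2% for H3K4me2. Sonication differences were 5.46 points at 50 °C and 1.74 at 65 °C, and the temperature difference at 5 min was 3.58. Recovery was 34.7%, 67.4%, 65.7% and 65.9%, with 8.46% for H3K4me2 and 0.0477% at 80 °C. The H3K4me2 overlap was 11.2%, 13.5% and 13.0% with the first 3.

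Of the large fresh frozen regions, stitching at 5000 bp gave shares of 13.8%, 17.4%, 14.4% and 16.3%, and 0.871% for H3K4me2. The 500 highest regions gave 32.8%, 36.2%, 35.2% and 35.7%, and 8.60%. Ranking by length gave 36.8%, 51.4%, 50.5% and 43.3%, and 13.2%. Leaving out either library of the pair left values from 56632 to 60244 peaks, 57.9% to 60.4% overlap with fresh frozen liver, 70.2% to 73.0% recovery, 25.9% to 26.3% of large regions and 19.5% to 21.0% H3K4me2 overlap. The sonication differences at 65 °C ranged from 3902 to 7514 peaks and from -4.20 to -1.64 points. The temperature differences at 5 min ranged from 18223 to 21835 peaks and from 10.3 to 12.9 points.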

Other observations

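The tests on co-marking, on removal of chromosome Y and on an animal without that chromosome were chosen after the values were seen. For the test on read pile-up, written before, the lists that had to show it were settled only after. H3K27Ac peaks were densest on chromosomes 11 and 19 in fresh frozen liver and in each of the 5 long FiTAc-seq lists. Fresh frozen liver had 31.0 peaks per Mb on chromosome 19 and 28.7 on chromosome 11, and the pair at 65 °C and 5 min had 39.1 ± 1.78 and 39.0 ± 2.06 (SD, n = 2). Chromosome X had fewer peaks per Mb than any autosome in these lists, with 5.70 peaks per Mb in fresh frozen liver, 4.91 ± 0.13 (SD, n = 2) in the pair and 1.91 at 50 °C and 5 min. Recovery of fresh frozen peaks on chromosome X was below that of autosomal peaks of like rank in each of the 5 long FiTAc-seq lists. It was 62.4% against 67.0% and 57.3% against 63.4% in the pair, and 22.7% against 37.3% at 50 °C and 5 min. The 1788 H3K4me2 peaks that met no H3K27Ac peak of fresh frozen liver or of a long FiTAc-seq list had a median width of 210 bp, against 248 bp for the others.

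The −log10 q-values of the lists differed in form. Fresh frozen liver had 24119 distinct values, the H3K4me2 list 2251, and the long FiTAc-seq lists between 388 and 982.

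The FiT-seq H3K27Ac peaks lay on FiT-seq H3K4me2 peaks in 104 of 115 cases. Co-marking of liver regulatory regions was argued against, since 5 of the 5 long FiTAc-seq lists held a smaller share of the 115 than of the other H3K4me2 peaks. At 65 °C and 40 min, for instance, it was 36.5% against 68.5%. These shares are of all 115, including those that met no H3K4me2 peak. Read pile-up that does not depend on the antibody stays open, as the H3K4me2 peaks concerned had a median rank at 0.783% from the top of their list and made up 56 of its 100 highest. The test also asked that the FiT-seq peaks be rarer than other H3K4me2 peaks among the 5000 highest H3K27Ac peaks, which held in the 5 long FiTAc-seq lists (0% to 10.4%, against 15.9% to 26.3%) but not in fresh frozen liver (21.7% against 21.3%). Input DNA was not analysed here, and no biological explanation other than co-marking was tested.

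None of the 5 long FiTAc-seq lists held a chromosome Y peak, whereas the fresh frozen list held 73. Lower sensitivity of the FFPE lists was argued against, because recovery at the rate of autosomal peaks of like rank would have given at least 29.0 of the 73 in each list. Removal of chromosome Y from all FFPE lists was argued against by 10 peaks there, 9 at 80 °C and 40 min and 1 for H3K4me2, all between 2765684 and 2889969. FFPE tissue from an animal without a Y chromosome could not be told apart from removal in those 5 lists alone, which was not tested. No FFPE list had a peak below 1 Mb, where fresh frozen liver had 6, but the H3K4me2 list would have held only 2.10 of these at its autosomal rate.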
